A study of Homo sapiens with 32 samples.

How the data were processed

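RNA of THP-1 cells, a human monocytic line, was measured on 32 Illumina HumanRef-8 arrays after 24 h with PBS, LPS at 100 ng/ml, TGFβ1 at 1 ng/ml, or LPS and TGFβ1 together, with 8 arrays per treatment. Treatments and replicate numbers were taken from the sample titles. The 32 arrays lay on 4 chips, and each chip held 2 arrays of each treatment. Nothing in the labels states that the arrays came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Per the labels, each treatment sat at fixed positions of its chip, so treatment and position cannot be told apart; the position labels of 4 LPS+TGFβ1 arrays repeat those of TGFβ1 arrays.

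The values used were the deposited intensity values of the series' value table, on a linear scale, 1 column per array. BeadStudio 3.2 is named in the submitters' processing notes, without a role; the background correction and the normalization are not given in the sources used here. The column medians ranged from 34.5 to 59.3, the upper quartiles from 345 to 381, and the lowest value was -35.4. Values below 0 and the nearly equal upper quartiles are what subtraction of background and a normalization between arrays would leave, but whether the values were centred, and on what scale factor, stays unknown. A deposited table of non-normalized signal and detection p-values has 64 columns headed by names that match no label of any sample. These columns were not used, and the normexp background correction and quantile normalization planned on them were not run; the plan named the series' value table for this case.

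Values were set to log2(intensity + 50). A fold change on this scale understates the change of dim genes. Probes whose mean log2 over all arrays lay in the lowest 25% were left out, which kept 18388 of 24518 probes. Gene symbols came from the platform annotation, updated through the gene number where the reference table held it (0 symbols changed). Of all probes, 21826 had 1 symbol, 0 had several and 2692 had none; probes without a symbol were tested and not named. A probe was called above background on an array where its intensity passed the mode of the dim values by 3 SDs of the values left of the mode. By that rule 12148 to 13517 probes were above background per array. A gene below background on all 8 arrays of 1 group is given as "at least N-fold". Its bound compares the bright group's mean log2 with the mean over the dim group's arrays of the higher of the lowest signal above background and the probe's own.

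Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group means over all 32 arrays, no covariate, two-sided), with the Benjamini-Hochberg adjusted p under 0.05 within each comparison. The 6 comparisons were LPS with PBS, TGFβ1 with PBS, LPS+TGFβ1 with PBS, with LPS and with TGFβ1, and the interaction, which is the log2 effect of LPS in the presence of TGFβ1 minus that in its absence. Probes raised or lowered at least 2-fold by LPS were counted as lower, higher or not called in LPS+TGFβ1 compared with LPS. Errors of log2 changes are standard errors of the fit, and errors of intensities are SDs. The number of arrays limits the precision.

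The 19 gene lists covered inflammatory cytokines and chemokines, the NF-kB pathway and its feedback, interferon-stimulated genes, TGFβ-SMAD target genes, TLR4 receptor and adaptor components, TGFβ receptor and SMAD components, monocyte and macrophage surface markers, MHC class II and class I presentation, matrix proteases and inhibitors, anti-inflammatory and alternative activation genes, NADPH oxidase and oxidant defence, the cell cycle, cholesterol synthesis and uptake, glycolysis and the hypoxia response, heat shock and the unfolded protein response, metallothioneins, markers of other lineages, and housekeeping genes. Each was tested with limma's camera at a preset correlation of 0.01 and again with the correlation estimated from the residuals, adjusted over the 19 lists within a comparison. List tests within a set used the preset correlation and were repeated with a correlation estimated within that set. Each gene was represented by its probe with the highest mean over all arrays. Genes named in the text followed a rule: the 6 largest rises and 6 largest falls with adjusted p under 0.05 and the same sign on all 4 chips; the 2 largest changes of each list, for every comparison except LPS+TGFβ1 with PBS and with TGFβ1; and always a fixed group of genes that included TNF, IL1B, IL6, CXCL8, CXCL10, CCL2, CD14, TLR4, SMAD7, TGFBI and TGFB1. Fewer genes are named than the rule allows. The comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined; other offsets and scalings, the stricter filter, the removal of PBS replicate 8 and everything that uses the 2 sets of arrays were added later.

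The arrays of every treatment parted into 2 sets along the first principal component of the residuals, which held 42.7% of their variance over 8000 probes with no called change. Set 1 held 14 arrays (3 PBS, 4 LPS, 3 TGFβ1 and 4 LPS+TGFβ1) and set 2 held 18 (5, 4, 5 and 4). The sets were found in the data and are named in no label. Fits within a set or with the set as a block therefore have a smaller spread by construction, and their p-values can be too small. Whether replicate numbers pair the arrays was read from the residuals of same-numbered arrays. These correlated at 0.517 to 0.678 between LPS and LPS+TGFβ1 and at 0.143 to 0.724 between PBS and TGFβ1. The numbers were therefore taken to pair the arrays in these 2 comparisons. The main fits did not use this pairing, and a fit with the replicate number as a block was an alternative. In the other comparisons, number 7 had negative correlations. The labels do not say what a number stands for. Arrays of the same set with different numbers correlated nearly as well (means of 0.528 and 0.389, compared with 0.595 and 0.458 for the same number), and each number lay on 1 chip. Every comparison was repeated within each set, with the set as a block, with the chip as a block and within each chip. Other alternatives were a fit of only the groups compared, other offsets, filters and scalings, array weights, the replicate number as a block, and leaving out each chip or replicate number.

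The fit was tested on simulated data for the comparison of LPS with PBS over 18388 probes. Of 50 probes changed by a log2 of 0.5, 84% were called in the right direction, as were 98% at a change of 1 and 100% at changes of 2 and of 4. Of 18188 unchanged probes, 6 were called. For TGFβ1 with PBS, 1 of the 19 lists was moved, and camera called 1 list, the moved one. The simulated values were drawn separately for each probe and array, without the 2 sets of arrays and without correlation between genes. These rates of false calls may therefore not hold for the real arrays.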

Results

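Expression in THP-1 cells was profiled on 32 arrays, 8 for each of 4 treatments: PBS as the control, LPS, which is a bacterial cell wall component sensed through TLR4, TGFβ1, a cytokine that signals through SMAD proteins, and LPS with TGFβ1. The series asked what happens when both pathways are active at the same time. Each array had between 12148 and 13517 probes above background. The arrays of every treatment fell into 2 sets, of 14 and 18 arrays, with a median SD between arrays of 1 treatment of 0.14 log2 units within a set and 0.29 between sets. Values within the sets are therefore given for the counts and for some genes and lists. Set 1 held 3 of the 8 arrays of PBS and of TGFβ1, and 4 of the 8 of LPS and of LPS+TGFβ1. Pooled changes of a group with LPS against one without it thus carry part of the difference between the sets. Because the sets were drawn from these same arrays, p-values within a set or with the set as a block can be too small. A call gained there is not independent support. Of 200 named gene changes, 59 differed by more than 1 log2 unit between the sets. Not all of these are given by set.

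To find what LPS alone did in 24 h, the LPS arrays were compared with the PBS arrays. IL1B, which encodes the inflammatory cytokine interleukin-1 beta, rose from an intensity of 61.4 ± 19.7 to 28680 ± 2540 (SD, n = 8 arrays each), a log2 change of 8.03 ± 0.18 (adjusted p = 4.54e-27). The chemokines CCL8 and CXCL10 and the interferon-induced gene IFI27 had log2 rises of 7.39 ± 0.62, 7.15 ± 0.47 and 7.10 ± 0.47, with 2, 1 and 3 of the 8 PBS arrays above background. Their rises were 5.91, 5.73 and 5.35 in set 1 and 9.02, 8.64 and 8.66 in set 2. IGFBP3, which binds insulin-like growth factors, was below background on all 8 PBS arrays and was at least 159-fold higher with LPS by its brighter probe and at least 104-fold by the other. The largest falls were in MS4A3, a membrane protein of myeloid progenitors (log2 changes of -4.05 ± 0.33 and -3.87 ± 0.37 by its 2 probes), KIT, the stem cell factor receptor (-3.16 ± 0.44), SERPINB10 (-2.96 ± 0.21), CEACAM6 (-2.86 ± 0.44) and CAT, which encodes catalase (-2.79 ± 0.16). Within set 1 the MS4A3 probes changed by -2.79 and -2.40 and KIT by -1.70, and within set 2 by -5.16, -5.26 and -3.98. SERPINB10 and CEACAM6 were above background on 5 and 4 of the 8 LPS arrays. KIT fell from 1608 ± 1060 to 88.5 ± 17.2 in intensity, and the dimmer MS4A3 probe from 4165 ± 1060 to 251.9 ± 195 (SD, n = 8 each).

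Inflammatory genes rose together. Of 21 measured inflammatory cytokines and chemokines, 18 rose and 3 did not pass the test, or 20 rose adjusted over the list alone (camera adjusted p = 4.22e-15, and 0.00106 with an estimated correlation). CCL2, a monocyte chemoattractant, rose by 6.22 ± 0.40 on the log2 scale, CXCL8, a neutrophil chemoattractant, by 2.88 ± 0.16, and TNF by 3.36 ± 0.56, from 1071 ± 1060 to 8443 ± 3520. The TNF rise was larger in set 2 than in set 1, by 1.39 ± 0.21 log2 units. IL6 was below background on all PBS arrays and was at least 19.3-fold higher with LPS. Of 21 NF-kB pathway and feedback genes, 19 rose, also adjusted over the list alone (adjusted p = 6e-20, and 0.00019 with an estimated correlation), among them SOD2, the mitochondrial superoxide dismutase (4.81 ± 0.16), and TNFAIP3, a feedback inhibitor of NF-kB (4.07 ± 0.11). All 43 measured interferon-stimulated genes rose, also adjusted over the list alone, with a median log2 change of 3.48 (adjusted p = 1.28e-27). Their camera call was lost with an estimated correlation over all arrays (adjusted p = 0.0807, and 0.0907 with the set as a block) and held with one within set 1 (8.64e-05) and set 2 (1.91e-05). The median rise of these genes was 2.24 in set 1 and 5.01 in set 2, and it lay between 2.26 and 4.98 within the 4 chips.

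Surface and effector genes of macrophages changed as well. The TLR4 receptor and adaptor list had 15 rises and 3 falls among 23 genes, 16 and 3 adjusted over the list alone (adjusted p = 7.93e-06, and 0.00556 with an estimated correlation). CD14, the LPS co-receptor, went from 307.5 ± 130 to 11310 ± 2060, and IRAK2, a kinase downstream of TLR4, rose by 4.33 ± 0.22. TLR4 itself had a log2 change of 0.59 ± 0.31, which did not pass the test (adjusted p = 0.13). It did with the chip as a block (adjusted p = 0.0348) and with the replicate number as a block (adjusted p = 0.000888). It also did with the set, which was drawn from these data, as a block (0.74, adjusted p = 4.49e-07). Of 27 monocyte and macrophage surface markers 22 rose and 2 fell, or 22 and 3 adjusted over the list alone (adjusted p = 4e-08, and 0.0103 with an estimated correlation), and CD80, a T cell costimulatory ligand, was at least 16.9-fold higher. Matrix proteases and inhibitors had 13 rises and 2 falls among 18 genes, the same adjusted over the list alone (adjusted p = 1.81e-05, and 0.00106 with an estimated correlation), led by MMP9, a gelatinase (5.65 ± 0.38, 5 of 8 PBS arrays above background), and ADAMDEC1 (5.22 ± 0.40). NADPH oxidase and oxidant defence genes had 13 rises and 1 fall among 18, 14 and 1 adjusted over the list alone (adjusted p = 4.19e-06, and 0.00106 with an estimated correlation); HMOX1, which degrades haem, was at least 16.6-fold higher. MHC class II genes rose in 9 of 11 cases, also over the list alone (adjusted p = 0.0021; adjusted p = 0.289 with an estimated correlation, or 0.0128 in set 1 and 0.00519 in set 2). MHC class I genes rose in 13 of 16, also over the list alone (adjusted p = 1.81e-05; adjusted p = 0.225 with an estimated correlation, or 0.238 in set 1 and 0.0178 in set 2). The MHC class I median was 0.29 in set 1, where 10 rose, and 1.55 in set 2, where 15 rose. HLA-DRA, an MHC class II chain, rose by 2.46 ± 0.37 and TAP1, a peptide transporter of class I loading, by 2.30 ± 0.29, or 1.26 in set 1 and 3.32 in set 2. Anti-inflammatory and alternative activation genes split into 10 rises and 2 falls among 17, 10 and 3 adjusted over the list alone (adjusted p = 0.0184; adjusted p = 0.0886 with an estimated correlation). IL1RN, the interleukin-1 receptor antagonist, rose by 2.38 ± 0.44 (1.06 in set 1 and 3.66 in set 2). F13A1, a coagulation factor subunit, changed by -2.49 ± 0.17 with 4 of 8 LPS arrays above background.

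In total, LPS raised 3848 and lowered 3857 of 18388 probes, and 936 and 436 of these at least 2-fold. With the arrays scaled to a common median, 3066 rose and 4741 fell. Within the sets, 8378 probes were called in set 1 and 8619 in set 2, with 9461 when the set and 8826 when the chip was a block, and between 1613 and 7248 within the single chips.

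TGFβ1 alone was compared with PBS to find its own effect. C3, the central complement component, was below background on all PBS arrays and at least 21.1-fold higher with TGFβ1, at 1927 ± 496 (SD, n = 8). OLR1, a receptor for oxidised LDL, rose by 4.63 ± 0.34 on the log2 scale (adjusted p = 1.04e-12, 1 of 8 PBS arrays above background), by 3.44 in set 1 and 5.35 in set 2. NPTX1 rose by 4.52 ± 0.27, DNASE2, a lysosomal nuclease, by 4.50 ± 0.18, RGS16, a regulator of G protein signalling, by 4.05 ± 0.16, and VASH1, an inhibitor of angiogenesis, by 3.99 ± 0.10, from 103.5 ± 16 to 2402 ± 344. RGS16 was above background on 7 of 8 PBS arrays. The largest falls were in NIM1K, a kinase (-2.77 ± 0.23, 5 of 8 TGFβ1 arrays above background), MT2A, a metallothionein (-2.29 ± 0.29), CCNA1, a cyclin (-2.12 ± 0.11), CAV1, the coat protein of caveolae (-1.83 ± 0.14), and TIMP3, a metalloproteinase inhibitor (-1.81 ± 0.28).

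TGFβ-SMAD target genes had 15 rises and 3 falls among 36 measured, the same adjusted over the list alone (adjusted p = 3.93e-07, and 0.000924 with an estimated correlation). AXL, a receptor tyrosine kinase, rose by 3.03 ± 0.38, BHLHE40, a transcription repressor, by 2.02 ± 0.20, TGFBI, an extracellular matrix protein, by 1.39 ± 0.10, and SMAD7, the feedback inhibitor of the pathway, by 1.23 ± 0.11, with 6 of 8 PBS arrays of SMAD7 above background. These rises were not all particular to TGFβ1: with LPS alone SMAD7, AXL and TGFBI changed by 1.38, 2.36 and -0.66. TGFB1 itself was above background on none of the arrays, so its change could not be read. The TGFβ receptor and SMAD components had 5 rises and 3 falls among 20, 6 and 4 adjusted over the list alone (camera adjusted p = 0.0178, and 0.0718 with an estimated correlation). Camera gave this list 0.356 in set 1, 0.0338 in set 2 (0.232 there with an estimated correlation) and 0.0582 with the set as a block. TGFBR1, a receptor chain, rose by 1.28 ± 0.10. Matrix proteases and inhibitors had 6 rises and 1 fall among 18, 9 and 1 adjusted over the list alone (adjusted p = 5.07e-05, and 0.00192 with an estimated correlation), with CTSB, a lysosomal protease, up by 1.87 ± 0.15. Glycolysis and hypoxia response genes rose in 11 of 24 cases, 15 adjusted over the list alone (adjusted p = 1.01e-08, and 0.011 with an estimated correlation), among them PFKFB4, a regulator of glycolysis (1.25 ± 0.14), and DDIT4 (1.03 ± 0.16). Of 27 monocyte and macrophage markers 8 rose, or 9 adjusted over the list alone (adjusted p = 7.24e-05; adjusted p = 0.0718 with an estimated correlation, or 0.0324 in set 1 and 0.00248 in set 2). CSF1R, the receptor for macrophage colony-stimulating factor, was 2.82-fold higher. ALOX5, which makes leukotriene precursors, rose by 3.57 ± 0.08, and CYBB, the catalytic NADPH oxidase subunit, by 2.13 ± 0.14.

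Over all arrays, few inflammatory genes were called with TGFβ1 alone. Among the 21 cytokines and chemokines 3 rose, the same adjusted over the list alone (adjusted p = 0.0739), with 4 rises and 5 falls in set 1 (adjusted p = 0.264) and 4 rises and 1 fall in set 2 (adjusted p = 0.0435, and 0.333 with an estimated correlation). CCL20, a chemokine, was at least 5.96-fold higher, IL1B rose by 1.59 ± 0.18, and CXCL8 rose by 1.11 ± 0.16, although CXCL8 did not pass within set 1 (0.32, adjusted p = 0.25) and rose by 1.58 in set 2. TNF changed by -0.33 ± 0.56 (adjusted p = 0.805), and by -0.67 in set 1, where it was called (adjusted p = 0.0166), and -0.12 in set 2 (adjusted p = 0.442). CD14 rose by 1.94 ± 0.20, with 3.16 in set 1 and 1.21 in set 2. Of the 43 interferon-stimulated genes, limma called 0 at the adjusted threshold and 1 at an unadjusted p under 0.05, with a list median of 0.05 (adjusted p = 0.381). Within set 1, 5 of them rose (adjusted p = 0.264), and within set 2, 9 rose and 2 fell (adjusted p = 0.00936, and 0.232 with an estimated correlation). TGFβ1 raised 1386 and lowered 1048 probes, 278 and 65 of them at least 2-fold. The number called was 3306 in set 1, 3824 in set 2, 3701 with the set, 3201 with the chip and 3537 with the replicate number as a block, and 132 to 2681 within the single chips.

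**Figure D1:**
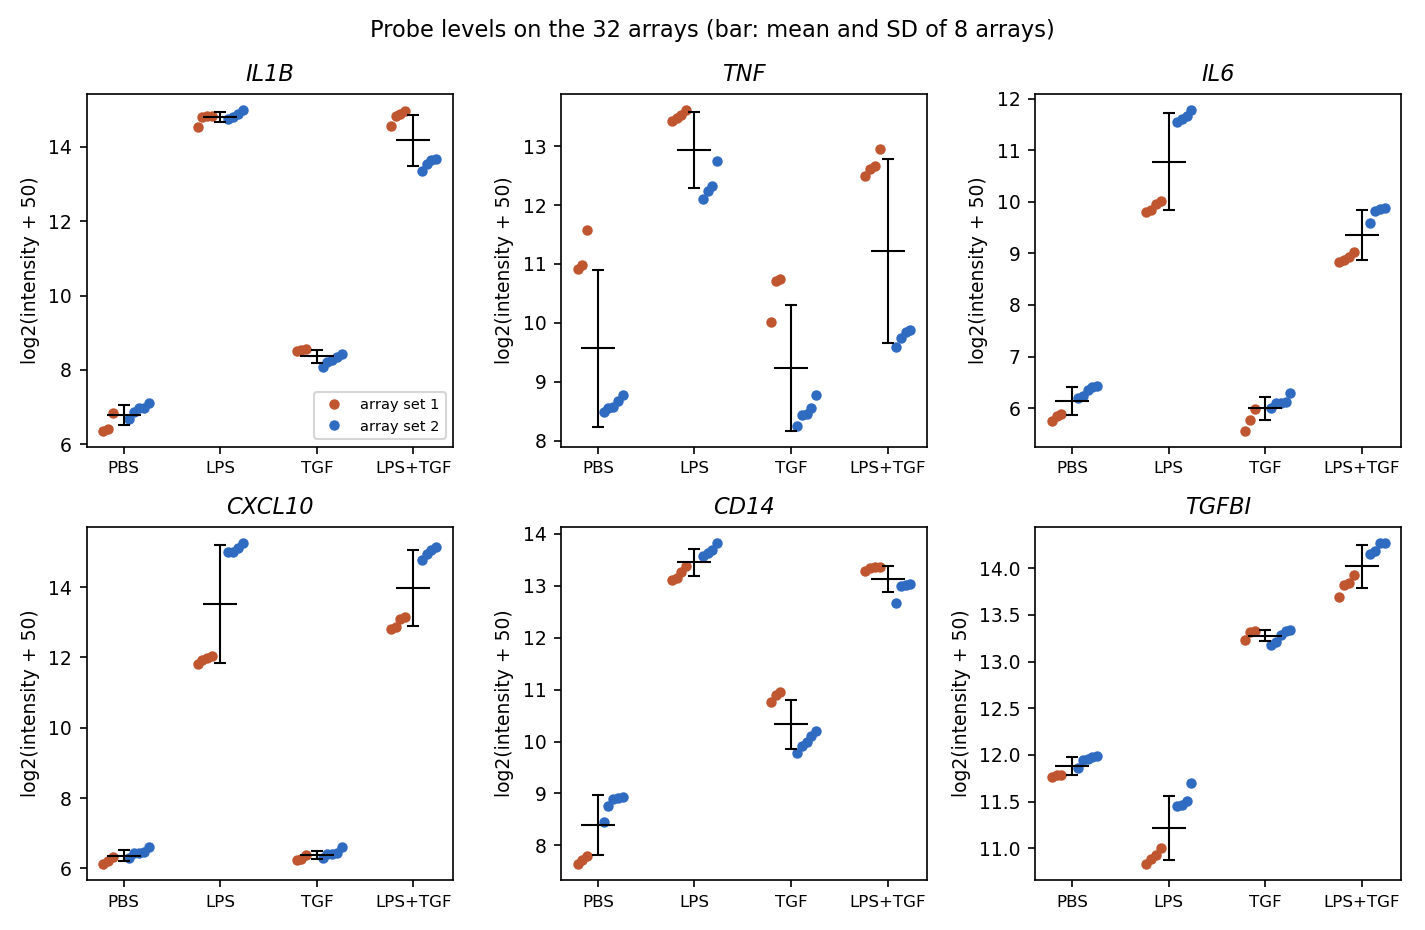
Levels of 6 genes on the 32 arrays, as log2(intensity + 50) by treatment, with 1 point per array coloured by array set and bars for the mean and SD of 8 arrays. IL1B, TNF, IL6, CXCL10 and CD14 lie higher with LPS than with PBS, and TGFBI lies highest with LPS+TGFβ1. The LPS+TGFβ1 arrays part by set in all 6 genes.

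The arrays with both stimuli were compared with each single stimulus and with PBS, to ask how TGFβ1 changes the response to LPS and LPS the response to TGFβ1. Adding TGFβ1 to LPS raised OLR1 by 4.79 ± 0.34, from 85.2 ± 22.6 to 3922 ± 1570 (SD, n = 8 each), and C3 by 4.02 ± 0.15, from 164 ± 56.7 to 3358 ± 589. RGS16, VASH1, the collagen gene COL15A1 and ALOX5 rose by 3.57 ± 0.16, 3.49 ± 0.10, 3.47 ± 0.11 and 3.39 ± 0.08. The largest falls were in DDIT4L (-2.32 ± 0.20), LILRB3, an inhibitory leukocyte receptor (-2.17 ± 0.21), C5AR1, the receptor for complement C5a (-2.11 ± 0.16), NIM1K (-1.92 ± 0.23), FFAR2, a receptor for short-chain fatty acids (-1.91 ± 0.13), and HES4, a transcription repressor (-1.83 ± 0.26). FFAR2 was above background on 6 of the 8 LPS+TGFβ1 arrays, and HES4 changed by -0.47 in set 1 and -3.18 in set 2.

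TGFβ-SMAD target genes had 14 rises and 4 falls among 36 on adding TGFβ1 to LPS, 17 and 6 adjusted over the list alone (adjusted p = 9.49e-06, and 0.00276 with an estimated correlation). TGFBI rose by 2.80 ± 0.10, from 2398 ± 581 to 16740 ± 2600, PMEPA1, a feedback inhibitor of the pathway, was at least 3.48-fold higher, and SMAD7 rose by 0.75 ± 0.11. Among NF-kB pathway and feedback genes 8 fell and 1 rose of 21, 9 and 1 adjusted over the list alone (adjusted p = 0.00781; adjusted p = 0.504 with an estimated correlation), with TNIP3, an inhibitor of NF-kB, at -1.43 ± 0.10. The NF-kB call was lost in set 1 (median -0.07, adjusted p = 0.586) and held in set 2 (median -0.31, adjusted p = 0.000184, and 0.00623 with an estimated correlation). Glycolysis and hypoxia response genes had 6 rises and 1 fall among 24, the same adjusted over the list alone (adjusted p = 0.013; adjusted p = 0.504 with an estimated correlation, 0.201 in set 1, and 0.00146 in set 2, where an estimated correlation gave 0.304). VEGFA, a growth factor for blood vessels, rose by 0.92 ± 0.10. CD80 changed by -1.61 ± 0.19, CD163, a scavenger receptor, by -0.97 ± 0.09, and IRAK2 by -1.25 ± 0.22, or -0.39 in set 1 and -2.12 in set 2.

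Inflammatory cytokines and chemokines had 8 falls and 1 rise among 21, 9 and 1 adjusted over the list alone, and the list did not pass (adjusted p = 0.0586). It had 6 rises and 6 falls in set 1 (adjusted p = 0.932) and 13 falls in set 2 (adjusted p = 2.7e-08, and 0.0256 with an estimated correlation). It passed with the set as a block (adjusted p = 0.0227; 0.707 with an estimated correlation) and with the replicate number as a block (adjusted p = 0.0492). IL6 changed by -1.43 ± 0.26, from 2041 ± 1220 to 636.3 ± 223, with -0.99 in set 1 and -1.86 in set 2, and IL23A, a subunit of interleukin-23, by -1.59 ± 0.18, with -0.80 in set 1 and -2.38 in set 2. TNF changed by -1.71 ± 0.56 (adjusted p = 0.0289), with -0.83 in set 1 and -2.58 in set 2. It was called with the chip as a block (adjusted p = 0.00252) and within each set, where p-values can be too small. Its pooled call was lost without chips 1, 3 or 4 (adjusted p = 0.0671, 0.143 and 0.103) and without replicate numbers 2, 5, 6 or 8 (0.0831, 0.0694, 0.0702 and 0.0811). IL1B changed by -0.63 ± 0.18 (adjusted p = 0.0129) over all arrays, by 0.06 in set 1 (adjusted p = 0.77) and by -1.31 in set 2 (adjusted p = 8.99e-10). The pooled IL1B call was also lost without chips 3 or 4 (adjusted p = 0.192 and 0.0511), without replicate numbers 2, 5, 6 or 8 (0.0787, 0.0576, 0.0589 and 0.0654) and in the fit of only the LPS and LPS+TGFβ1 arrays (0.0583). CXCL10 had a log2 change of 0.45 ± 0.47, CXCL8 of -0.07 ± 0.16, CCL2 of 0.02 ± 0.40 and CD14 of -0.32 ± 0.20, and none of these passed (adjusted p = 0.523, 0.796, 0.975 and 0.26). CXCL10 was called with array weights (1.70, adjusted p = 0.0015). That value is larger than the change within either set, so neither set alone shows it. Within set 1 CXCL10 rose by 1.03 (adjusted p = 1.32e-07) and within set 2 it changed by -0.12 (adjusted p = 0.309), and CD14 changed by 0.11 (adjusted p = 0.324) and -0.75 (adjusted p = 2.31e-05). TLR4 changed by -0.70 (adjusted p = 0.116), a change called with the chip as a block (adjusted p = 0.0252), with the replicate number as a block (adjusted p = 0.000439) and with the set as a block (adjusted p = 4.52e-06). Of 43 interferon-stimulated genes 1 was called, the fall of GBP2, also adjusted over the list alone (adjusted p = 0.609), and the GBP2 call was lost without chip 3 (adjusted p = 0.0828). In set 1, 24 of the 43 rose and 2 fell, with a median of 0.30 (adjusted p = 1.36e-08, and 0.0253 with an estimated correlation). In set 2, 1 rose and 18 fell, with a median of -0.22 (adjusted p = 3.98e-05). That call was lost with an estimated correlation (adjusted p = 0.109). The 33 cell cycle genes had 3 rises and 2 falls over all arrays (adjusted p = 0.154). They had 2 rises and 15 falls in set 1 (adjusted p = 0.00352, and 0.17 with an estimated correlation). Set 2 had 20 rises and 1 fall (adjusted p = 2.7e-08, and 0.000156 with an estimated correlation).

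Across all probes, adding TGFβ1 to LPS raised 1506 and lowered 1861, with 186 and 125 at least 2-fold. The balance of rises and falls depended on the scaling: with the arrays scaled to a common median 2074 rose and 1196 fell, and with quantile normalization 1630 rose and 1592 fell. The number called was 3662 in set 1, 5391 in set 2, 5432 with the set, 4770 with the chip and 5283 with the replicate number as a block, and 80 to 3232 within the single chips. Of the 936 probes that LPS had raised at least 2-fold, 306 were lower with TGFβ1 added, 126 were higher and 504 were not called. Of the 436 lowered by LPS, 105 were higher, 43 were lower and 288 were not called. Selection and test share the LPS arrays. With selection on chips 1 and 2 and the test on chips 3 and 4, 285 of 832 LPS-raised probes were lower and 77 higher, and 91 of 360 LPS-lowered probes were higher and 16 lower. With the chips exchanged, 173 of 1046 LPS-raised probes were lower and 107 higher, and 44 of 563 LPS-lowered probes were higher and 35 lower, so the excess was much smaller. Chips 1 and 2 held mostly arrays of set 1 and chips 3 and 4 mostly arrays of set 2, so this exchange was largely one of sets too. Within set 1, 272 of 775 LPS-raised probes were lower and 211 were higher, and within set 2, 634 of 1148 were lower and 148 were higher. Among LPS-lowered probes, 71 of 324 were higher and 90 lower in set 1, and 371 of 715 were higher and 68 lower in set 2.

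**Figure D2:**
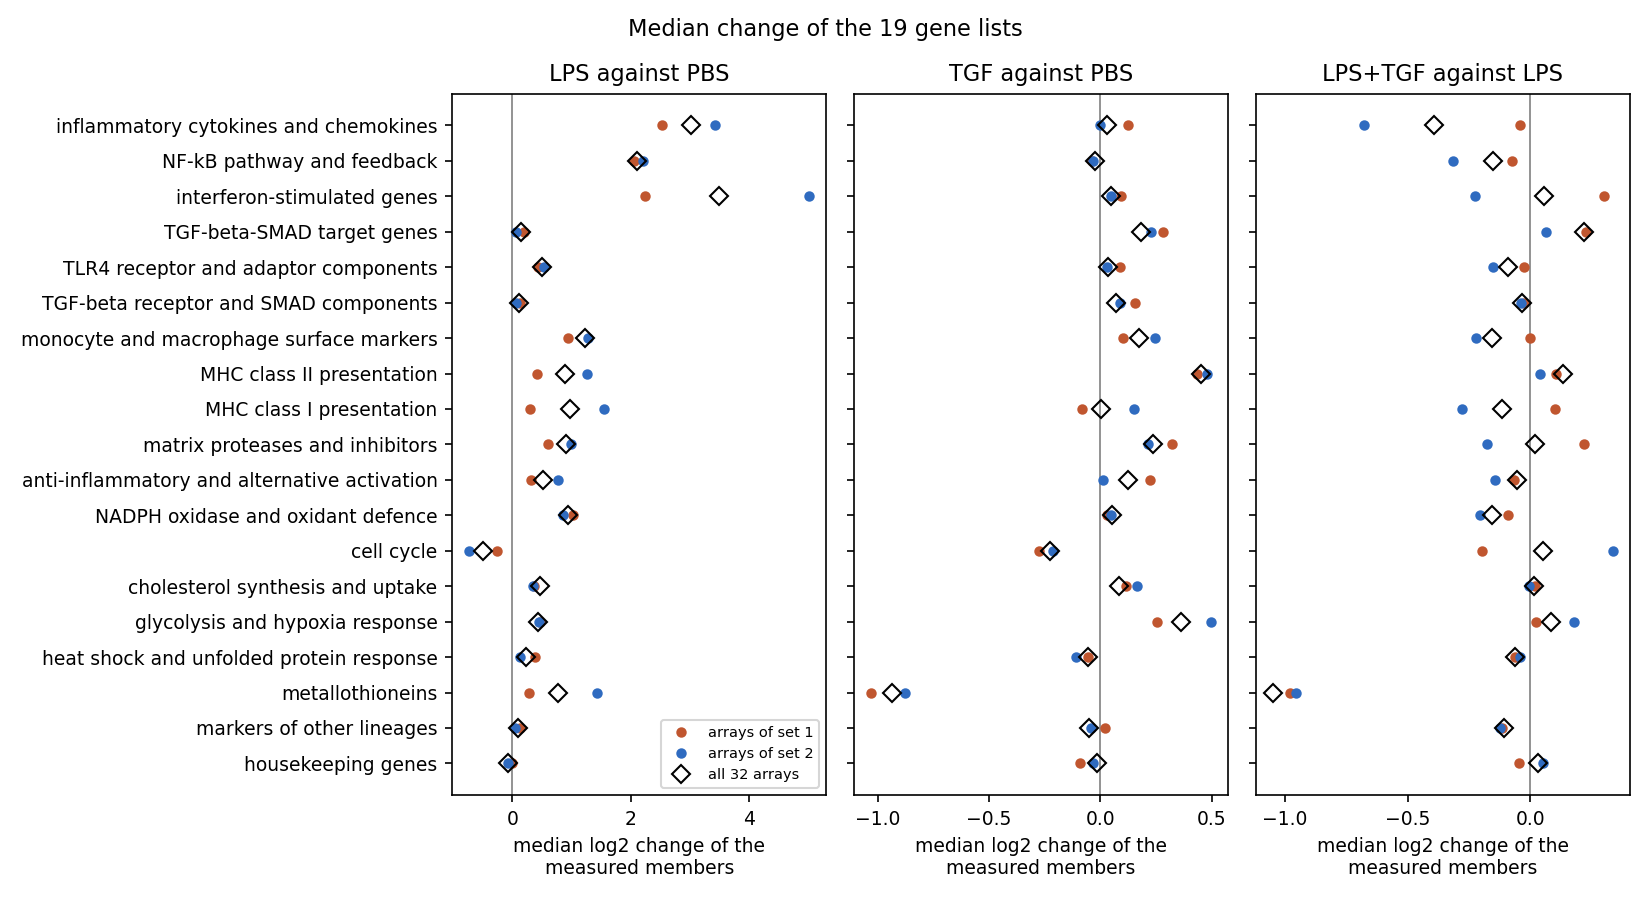
Median log2 change of the measured members of the 19 gene lists in 3 comparisons, with diamonds for all 32 arrays and points for the arrays of each set. Over all arrays, interferon-stimulated genes have the largest median with LPS, at 3.48, and metallothioneins the lowest with TGFβ1, at -0.94.

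Compared with PBS, both stimuli together gave log2 rises of 7.61 ± 0.47 in CXCL10, 7.40 ± 0.18 in IL1B and 6.65 ± 0.25 in RGS1, a regulator of G protein signalling above background on 4 of 8 PBS arrays. CXCL13, a B cell chemoattractant, was below background on all PBS and all TGFβ1 arrays and was at least 86.5-fold higher with both stimuli than with PBS and at least 88.1-fold higher than with TGFβ1. IGFBP3 was at least 119-fold above PBS. The largest falls from PBS were in BMP8B, a bone morphogenetic protein (-3.46 ± 0.31), SERPINB10 (-3.34 ± 0.21), PPP1R27 (-3.10 ± 0.49), MS4A3 (-3.06 ± 0.33), CCNA1 (-2.95 ± 0.11) and PHACTR3 (-2.87 ± 0.36). TGFBI and SMAD7 rose by 2.13 ± 0.10 and 2.13 ± 0.11. TNF rose by 1.66 ± 0.56 (adjusted p = 0.0165), a call lost without chip 4 (adjusted p = 0.13) and without replicate number 7 (adjusted p = 0.0848). Inflammatory cytokines and chemokines rose in 15 of 21 cases, 16 adjusted over the list alone (adjusted p = 1.55e-13, and 0.00132 with an estimated correlation), and all 43 interferon-stimulated genes rose, also adjusted over the list alone (adjusted p = 3e-31, and 0.0469 with an estimated correlation).

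Compared with TGFβ1 alone, both stimuli raised CXCL10 by 7.59 ± 0.47, EBI3, an interleukin-27 subunit, by 6.44 ± 0.16, and IFI44L, an interferon-stimulated gene, by 6.43 ± 0.39, with 1, 6 and 3 of 8 TGFβ1 arrays above background. The largest falls were in CEACAM6 (-3.36 ± 0.44), MS4A3 (-3.19 ± 0.33 and -3.05 ± 0.37 by its 2 probes), DEPTOR, an inhibitor of mTOR (-2.83 ± 0.07), CAMP, an antimicrobial peptide precursor (-2.71 ± 0.17), and FBP1, an enzyme of gluconeogenesis (-2.60 ± 0.14). CEACAM6 and CAMP were each above background on 4 of 8 LPS+TGFβ1 arrays. IL1B rose by 5.81 ± 0.18 and TNF by 1.98 ± 0.56, the TNF call being lost without chip 4 (adjusted p = 0.0528). With both stimuli 3313 probes were above and 4021 below PBS, and 2746 were above and 3042 below TGFβ1. Within the sets these totals were 7688 and 8863 against PBS and 6504 and 6686 against TGFβ1; with the set as a block they were 8601 and 7257, with the chip as a block 8346 and 6737, and within the single chips 1546 to 6998 and 683 to 5782.

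The interaction asked whether the log2 effect of LPS differed in the presence of TGFβ1. SRC, a tyrosine kinase, rose by 4.48 with LPS over PBS and by 1.41 with LPS+TGFβ1 over TGFβ1, an interaction of -3.07 ± 0.27 (adjusted p = 6.93e-10). CD14, C5AR1, IRAK2 and HMOX1 had interactions of -2.26 ± 0.28, -2.33 ± 0.22, -2.11 ± 0.32 and -1.89 ± 0.18, each with a smaller rise in the presence of TGFβ1. IL1B, with rises of 8.03 and 5.81, had an interaction of -2.22 ± 0.26 (adjusted p = 2.38e-07). TGFβ1 alone had raised CD14 and IL1B over PBS, by 1.94 and 1.59, which makes up most of these 2 interactions. MGLL, a monoglyceride lipase, and CAMP had interactions of -2.53 ± 0.16 and -2.56 ± 0.24. VCAN, a matrix proteoglycan, rose by 1.78 with LPS and by 1.72 with TGFβ1 alone, and its interaction was -2.45 ± 0.39. Among the largest positive interactions were those of FCRLA, an Fc receptor-like protein, at 2.06 ± 0.25, TGM5, a transglutaminase, at 1.99 ± 0.40 and 1.72 ± 0.34 by its 2 probes, CDC42EP4 at 1.75 ± 0.16 and NREP at 1.64 ± 0.18. FCRLA was below background on all arrays except those with both stimuli, and C5AR1, HMOX1 and MGLL were above background on 1, 0 and 0 of the 8 PBS arrays, so the sizes of these interactions depend on the offset of the log2 scale. IL1B was also dim with PBS, at log2 values of 6.37 to 7.10, so the size of its interaction depends on the offset too. TGFBI, which changed by -0.66 with LPS over PBS and rose by 0.74 with LPS+TGFβ1 over TGFβ1, had an interaction of 1.40 ± 0.15, and MYC, a growth-promoting transcription factor, one of 1.24 ± 0.17.

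Monocyte and macrophage surface markers had 9 negative interactions among 27, 14 negative and 1 positive adjusted over the list alone (adjusted p = 9.68e-06; adjusted p = 0.0683 with an estimated correlation). With an estimated correlation this list passed with the set as a block (0.0396), in set 1 (0.0229) and in set 2 (0.00153). Inflammatory cytokines and chemokines had 6 negative interactions among 21, the same adjusted over the list alone (adjusted p = 6.42e-05; adjusted p = 0.098 with an estimated correlation). That call was lost in set 1 (adjusted p = 0.088) and held in set 2 (adjusted p = 1.18e-14, and 0.00284 with an estimated correlation). Cell cycle genes had 5 positive interactions among 33, 8 positive and 1 negative adjusted over the list alone (adjusted p = 9.68e-06; adjusted p = 0.266 with an estimated correlation), a call also lost in set 1 (median 0.04, adjusted p = 0.129) and held in set 2 (median 0.54, adjusted p = 6.1e-12, and 1.77e-05 with an estimated correlation). TNF had an interaction of -1.38 ± 0.79 that did not pass (adjusted p = 0.361), with -0.16 in set 1 (adjusted p = 0.727), -2.46 in set 2 (adjusted p = 4.2e-10) and adjusted p = 0.000442 with the set as a block. The CXCL8 interaction of -1.17 ± 0.23 was -0.33 in set 1 (adjusted p = 0.42) and -1.71 in set 2. In all, 518 probes had a positive and 821 a negative interaction, but with the arrays scaled to a common median 774 were positive and 594 negative, so the excess of negative interactions depended on the scaling. The number called was 1746 in set 1, 3259 in set 2, 2559 with the set and 1981 with the chip as a block, and 0 to 1659 within the single chips. Chips 1 and 4 had 0 calls each in limma. Their 866 and 932 probes at an unadjusted p under 0.05 are near the number that 18388 tested probes would give with no effect. These 2 chips held arrays of both sets, while chip 2 held only arrays of set 1 and chip 3 only arrays of set 2. Spread between the sets thus enters the fits of chips 1 and 4, which had the lowest counts in every comparison.

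**Figure D3:**
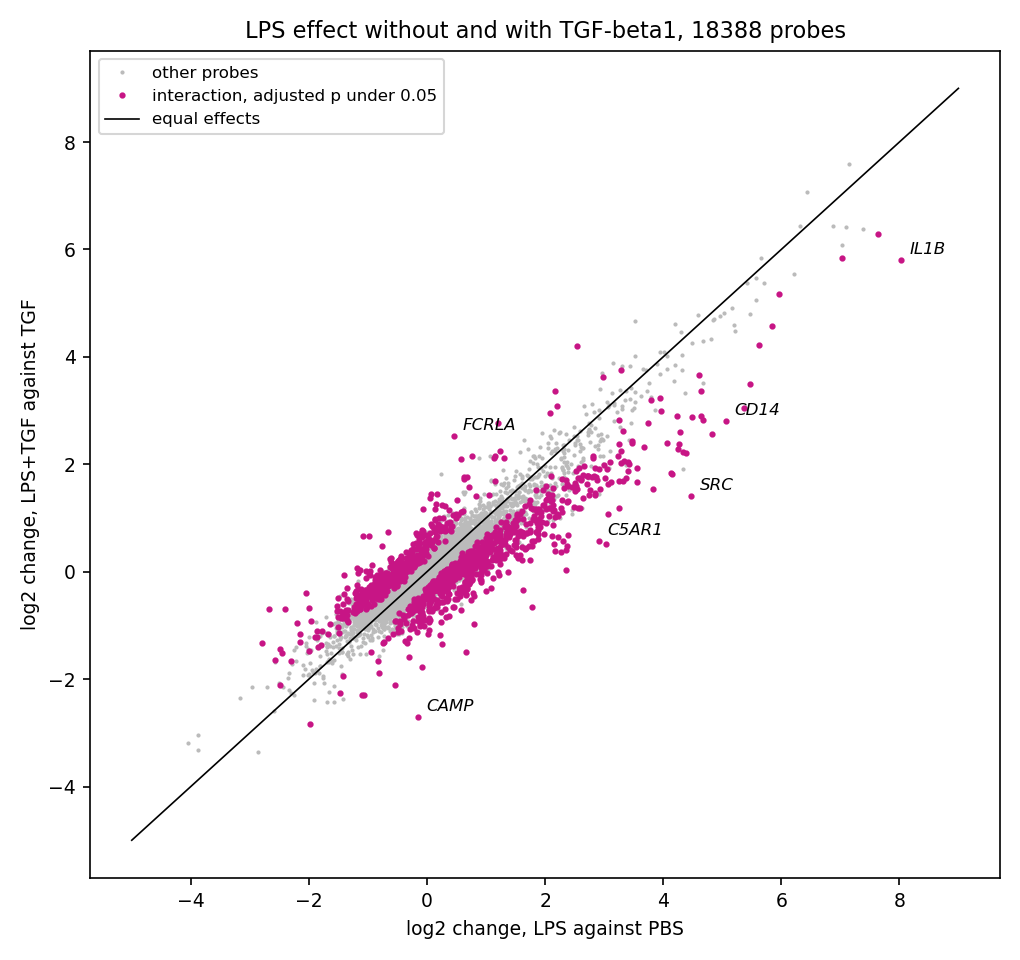
Log2 change of each tested probe with LPS over PBS (horizontal) and with LPS+TGFβ1 over TGFβ1 (vertical), with the 1339 probes called for the interaction in colour and a line of equal effects. IL1B, CD14, SRC, C5AR1 and CAMP lie below the line and FCRLA above it.

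The effects of LPS and of TGFβ1, each over PBS, overlapped. Both raised 683 probes, where independent lists would share 290, and both lowered 693, where independent lists would share 220; 373 probes went in opposite directions. The comparisons share the PBS arrays. With these split between the comparisons, odd numbers to LPS or even numbers to LPS, 487 and 444 probes were raised by both and 419 and 361 lowered by both, where independent lists would share 202 and 171, and 132 and 106. Across probes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.3 and a covariance of 0.0608. Groups simulated without any effect against shared controls gave a correlation of 0.502, a covariance of 0.007 and 0 shared calls. On average over 50 draws, 0 probes were called raised by LPS or by TGFβ1, 0 lowered by LPS and 0.04 lowered by TGFβ1. With next to no calls to share, the 0 shared calls followed by construction. They cannot say how many shared calls the shared PBS arrays or the sets of arrays would give.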

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

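The counts for other splits of the arrays were planned in kind but judged after the real counts had been seen, and the test of the array scale's upper end was chosen after values of single genes had been seen.

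The LPS effect differed in the presence of TGFβ1 for 1339 probes, 518 with a positive and 821 with a negative interaction in limma. Of 100 splits of the 32 arrays into 4 groups of 8, 2 gave as many probes, the real one included, and the highest other split gave 1495. In that split, the groups in the places of PBS and LPS+TGFβ1 held 5 and 7 LPS-treated arrays and those in the places of LPS and TGFβ1 held 2 each, so it partly followed LPS treatment. The splits mixed the arrays of all 4 treatments, so they also moved the effects of LPS and of TGFβ1 themselves. The share of splits therefore says little about the interaction alone, and chance is left open for this count. SRC, CD14, C5AR1 and IL1B were among the genes whose rise was smaller with TGFβ1, and TGFBI and FCRLA among those with a positive interaction. For CD14 and IL1B most of this lay in a higher starting level, as TGFβ1 alone raised them over PBS by 1.94 and 1.59 log2 units. Adding TGFβ1 to LPS changed CD14 by -0.32 (limma adjusted p = 0.26), IL1B by -0.63 and C5AR1 by -2.11.

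CCL8, a monocyte chemoattractant, had 1 TGFβ1 array far from the others, replicate 7 at an intensity of 94.3 with the other 7 between 6.69 and 39.7; the gap was 0.624 of the whole range. CXCL8 had 1 such PBS array, replicate 1 at 8510 with the others between 5170 and 6190, a gap of 0.695 of the range. Chance gives about 1 such array in 20 groups, or 3.6 in the 72 groups of values examined, and 2 were found.

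A TGFβ1 effect that differs between the 2 sets of arrays was seen in the LPS response. The difference was called for 485 of the 936 probes raised at least 2-fold by LPS, and for 457 of them the effect of TGFβ1 was more negative or less positive in set 2; the sets were themselves found in these data. A ceiling of the array scale might flatten such differences in set 1, but 382 of the 485 probes had LPS means under an intensity of 5000 in both sets, which argues against a ceiling as the whole cause. IL1B was among the 485 with LPS means over 5000 in both sets. For IL1B a ceiling is therefore left open. The arrays numbered 7, which belong to set 2 for PBS and TGFβ1 and to set 1 for LPS and LPS+TGFβ1, were left out in turn, and 433 of the 485 were called again. Over all probes, 1944 differed between the sets in LPS+TGFβ1 against LPS, and 6 of 100 regroupings of the arrays gave as many, the highest other 6343; for LPS against PBS 4707 differed, 2 of 100 gave as many, and the highest other was 7233. In the highest regrouping of each comparison 0 of 8 arrays of one treatment and 6 of 8 of the other kept their set. Each other regrouping with as many kept or exchanged the whole sets in 1 treatment, so these regroupings carry the difference in level between the sets. Their share therefore says little about chance, which is left open for both counts. No biological explanation was tested, because the design names none for the sets.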

How the results depend on the processing

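All alternatives that use the sets of arrays, other offsets, another scaling, the filter at the median or the removal of PBS replicate 8 were chosen after seeing the data. Of 5569 values of 200 named gene changes under the alternatives, 5417 kept their side of the threshold, 133 lost the call, 18 gained one and 1 reversed: IL1B in LPS+TGFβ1 against LPS had a log2 change of 0.0565 in set 1 alone. A turn of sign was counted as reversed only where the main or the alternative value was called. The 5417 thus include turns of sign without a call, such as CXCL10 in set 2 and CD14 in set 1 in that comparison. Quantile normalization, scaling to a common median, chip as a block, robust eBayes, the 2-group fit and the filters kept all total counts of changed probes within 1.5 times, though scaling turned the balance of rises and falls. Counts below are for TGFβ1 against PBS, LPS+TGFβ1 against LPS and the interaction unless stated. With the set as a block they were 3701, 5432 and 2559, in set 2 alone 3824, 5391 and 3259, with array weights 4373, 5532 and 2925, and at adjusted p under 0.01 1578, 2048 and 658. At least 2-fold, the 6 comparisons had 1372, 343, 1369, 311, 903 and 191 probes. LPS+TGFβ1 against LPS and the interaction gave 2189 and 651 without chip 1 and 2046 and 559 without chip 3; the interaction gave 834 without chip 4. Without 1 replicate number at a time, the interaction ranged from 809 (number 5) to 1158 (number 3), and it gave 1356 without PBS replicate 8. LPS-raised probes lowered by TGFβ1 numbered 634 in set 2, 549 at a 1.5-fold selection and 173 when selected on chips 3 and 4; LPS-lowered probes raised by it numbered 371, 301 and 44, 53 without chip 3 and 159 with values under 16 set to 16. Stricter thresholds lower counts by construction; otherwise the cause was not tested. Of 114 list tests 66 were called, 29 with an estimated correlation, 36 with that and the set as a block, and with that 41 in set 1 and 59 in set 2. With the PBS arrays split, probes changed alike by LPS and TGFβ1 numbered 906 and 805 instead of 1376. Replicate numbers were not taken to pair the arrays outside TGFβ1 against PBS and LPS+TGFβ1 against LPS: 4 of 48 same-numbered pairs, all of number 7, correlated at or under 0.1, and 15 of 32 arrays matched their own number best. The replicate block gave 5283 probes for LPS+TGFβ1 against LPS and 2342 for the interaction, and other counts stayed within 1.5 times. It also changed the calls of TLR4 with LPS (adjusted p = 0.000888) and with LPS+TGFβ1 against LPS, of TUBB with TGFβ1 (0.0527), of the TNF interaction (0.0199) and of 3 list tests, and no other call of a named gene or list. The alternatives of no background correction, other background offsets, median scaling of background-corrected signal and a detection p filter were not run, since they need the unmatched non-normalized columns; the series' value table, planned as an alternative, became the data used. Signal over background limits genes such as IL6, C3 and IGFBP3 to bounds.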

Other observations

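The tests of chip, of background and scaling for the sets and of a wrong label for PBS replicate 8 were chosen after the results had been seen, as were those of the splits; the test of scaling for PBS replicate 8 was not.

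Metallothioneins, which bind zinc and copper, rose with LPS and fell with TGFβ1 over all arrays. LPS raised 6 of 8, also adjusted over the list alone (camera adjusted p = 0.0338; adjusted p = 0.409 with an estimated correlation), and MT2A by 3.53 ± 0.29. The rise was lost in set 1 (2 of 8, median 0.27, adjusted p = 0.138) and held in set 2 (7 of 8, median 1.43, adjusted p = 0.00174, and 0.169 with an estimated correlation). TGFβ1 lowered 4 of 8, 5 adjusted over the list alone, with a median of -0.94 (adjusted p = 0.000777; adjusted p = 0.268 with an estimated correlation). MT1G changed by -1.61 ± 0.26 with TGFβ1 alone and by -1.46 ± 0.26 when TGFβ1 was added to LPS, where 5 of 8 fell, 6 adjusted over the list alone (adjusted p = 0.00781; adjusted p = 0.562 with an estimated correlation). Cell cycle genes fell with LPS in 24 of 33 cases and rose in 2, 25 and 2 adjusted over the list alone (adjusted p = 1.18e-06; adjusted p = 0.166 with an estimated correlation, or 0.0638 in set 1 and 4.54e-05 in set 2). MCM4, a helicase subunit, changed by -1.09 ± 0.13, while CCND1, a cyclin of the G1 phase, rose by 2.59 ± 0.23. With TGFβ1 alone 6 of the 33 fell and 1 rose, 8 and 1 adjusted over the list alone (adjusted p = 0.000838; adjusted p = 0.412 with an estimated correlation, or 0.0261 in set 1 and 0.0108 in set 2).

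LPS also changed sugar metabolism genes and single genes of the stress response. Glycolysis and hypoxia response genes rose in 15 of 24 cases, also adjusted over the list alone (adjusted p = 7.93e-06, and 0.0408 with an estimated correlation). That last call held in set 1 (0.0116) and was lost in set 2 (0.116) and with the set as a block (0.0505). Among them were SLC2A3, a glucose transporter, up by 2.29 ± 0.09 and ADM, the gene of adrenomedullin, up by 2.71 ± 0.16 and above background on 4 of 8 PBS arrays. Among 23 heat shock and unfolded protein response genes 10 rose and 3 fell, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.0602) except in set 1 (0.00672, and 0.0727 with an estimated correlation); ATF3, a stress-induced transcription factor, rose by 2.78 ± 0.25, or 1.78 in set 1 and 3.70 in set 2. With TGFβ1 alone XBP1, a regulator of the unfolded protein response, changed by -0.96 ± 0.12. Cholesterol synthesis and uptake genes had 6 rises among 17 with LPS, the same adjusted over the list alone, and did not pass (adjusted p = 0.0826). This list did pass with the set as a block (adjusted p = 0.000117, and 0.0104 with an estimated correlation), with the chip as a block (0.0304) and within both sets (0.00432 and 0.000619, and 0.0721 and 0.0178 with an estimated correlation). TGFβ-SMAD target genes had 11 rises and 9 falls among 36 with LPS, 12 and 9 adjusted over the list alone (adjusted p = 0.0699; 0.0146 in set 2, and 0.0365 there with an estimated correlation), and the TGFβ receptor and SMAD components 6 rises and 3 falls among 20, the same over the list alone (adjusted p = 0.305). Markers of other lineages had 3 rises and 3 falls among 15, the same over the list alone (adjusted p = 0.969; median 0.09, with the test's direction down), MPO, the neutrophil granule peroxidase, at -1.29 ± 0.07 and NKG7 at 1.16 ± 0.13. Housekeeping genes had 2 rises and 4 falls among 11, the same over the list alone (adjusted p = 0.4).

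The 2 sets of arrays differed in the levels of many genes, some of them also changed by LPS. Over all treatments, HMGCS1 and LSS, enzymes of cholesterol synthesis, had mean intensities of 16070 and 5565 in the 14 arrays of set 1 and 3945 and 1586 in the 18 arrays of set 2, while ABCA1, a cholesterol exporter, had 778.7 and 3022. The cholesterol synthesis and uptake list had a median log2 difference of -1.06, set 2 minus set 1. TNF had means of 5994 and 1529, and BEX1 of 12340 and 3143. The shares of arrays with LPS differ, 8 of 14 and 8 of 18; with the treatments in the fit, the log2 differences of HMGCS1, LSS, ABCA1, TNF and BEX1, set 2 minus set 1, were -1.96, -1.77, 2.05, -2.15 and -2.46. These genes were chosen after their values were seen, and no p-value is given because the sets were drawn from the same data.

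What parted the arrays into sets stays open. The chip is argued against as the whole cause, since 2 of the 4 chips held arrays of both sets. Residuals of arrays on 1 chip but in different sets correlated at -0.156 on average, and those of arrays in 1 set but on different chips at 0.270. A different background level or overall scaling of the arrays could also part them, but 75 of 3506 probes with a mean over 1000 still differed at least 2-fold after quantile normalization. Separate cultures or days of treatment are named in no label, and no biological explanation was tested.

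PBS replicate 8 stood apart from the other PBS arrays of its set, with SDs of 0.243 to 0.291 log2 units against them where the median of such pairs was 0.138. A wrong treatment label is unlikely: of the 12 genes with the largest rises under LPS or TGFβ1, 0 lay at or above the lowest array of that treatment on this array. Background level or overall scaling is argued against as well, because its lowest SD was still 0.249 after quantile normalization, above the highest of the other pairs, 0.183. No biological explanation was tested, and the counts without this array stayed within 1.5 times.

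Of 100 splits of the arrays, only the real one gave as many changed probes for LPS against PBS (7705, the highest other 2949), LPS+TGFβ1 against PBS (7334 and 5191), LPS+TGFβ1 against LPS (3367 and 3014) and LPS+TGFβ1 against TGFβ1 (5788 and 3748). For arrays taken as separate units, chance is excluded for these 4 counts, each at 1 of 100, the lowest share that 100 splits can give. The labels do not state separate cultures, so chance between cultures is not excluded for any count given here. Only the real split also gave as many LPS-raised probes lowered by TGFβ1 (306 and 98) and LPS-lowered probes raised by it (105 and 21). In all splits these probes were those selected with the real LPS arrays, which favours the real split, so chance is left open for these 2 counts. For TGFβ1 against PBS 4 of 100 splits, the real one included, gave as many as the real 2434. Other splits thus reached that count, so chance is left open for it. The highest other split, with 4048, put 6 arrays of set 1 in one group and 0 in the other, and the count with the set as a block was 3701. The split that gave 3014 likewise had 1 and 7 arrays of set 1 in its groups. The number of gene lists called by camera with the preset correlation could not be told from other splits for LPS against PBS (13 lists, matched by 18 of 100 splits, the highest other 15), LPS+TGFβ1 against PBS (14, 19 splits, 15), LPS+TGFβ1 against LPS (4, 65 splits, 11) and the interaction (8, 38 splits, 15). For TGFβ1 against PBS (11, 4 splits, 13) and LPS+TGFβ1 against TGFβ1 (16, 2 splits, 16) the share of splits was low. The highest other split still gave as many lists or more, so chance is left open there too. With an estimated correlation, camera called 7, 3, 10, 1, 8 and 0 lists in the 6 comparisons, and for the interaction 5 lists had an unadjusted p under 0.05. The fry test of limma asks whether a list changed at all, where camera compares it with the other genes. It called 18, 13, 17, 10, 18 and 10 lists, so the 2 counts answer different questions.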
